A study of Mus musculus with 55 samples.

How the data were processed

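The series held bulk RNA sequencing of mouse pancreatic tumour cells with and without interleukin-1β (IL-1β), a cytokine that acts through the receptor Il1r1. K8484 is a line from a KPC mouse tumour (mutant Kras and a missense mutation of Trp53), DT6606 a line from a KC mouse tumour (mutant Kras), and the KPC organoids came from tumours with mutant Kras and a floxed Trp53. Cultures received 10 ng/mL IL-1β or were left untreated, the lines for 24, 48 or 96 h and the organoids for 8, 24, 48 or 72 h. Per the labels' protocols, purified RNA was reverse transcribed and amplified by Smart-seq2, tagmented and amplified again, a procedure that keeps no record of the strand and adds no molecular identifiers.

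The deposited values were raw read counts per gene symbol in 2 tables, 1 for both lines and 1 for the organoids, with no normalization. Per the submitters' processing notes, the tools were STAR 2.5.3a and featureCounts and the genome build was mm10; the notes state neither the annotation nor how multiply mapped reads were counted. All 55 libraries were matched to a column by the sample names in the labels, and 0 columns were left over. Of the 32245 symbols in the tables, 31490 were found in the GENCODE M21 annotation of GRCm38, the assembly also called mm10. Coordinates of all 349 named genes came from that annotation and are 1-based. Genes with close relatives or overlapping partners (the Saa, Sprr2, Clca3 and Serpina3 families, and Plet1 with its antisense gene Plet1os) are uncertain to the extent that reads could be shared between them.

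Library totals ran from 9410439 to 30097519 counted reads with a median of 15376904, and mitochondrially encoded genes took 1.36 to 3.08% of the reads. Replicates differed by a chi-square per degree of freedom of 2.95 to 67.3 across genes, so no pair of replicates within a group was a copy of the same library. Columns of different groups were not compared in this way. The highest value was that of stimulated DT6606 replicates 2 and 3 of 48 h, with 32.5 for replicates 1 and 2. Replicate 2 of that group also had the lowest TMM factor of all libraries (0.893), and its values are part of the group means given for 48 h. CPM values, counts scaled to a common library total, were computed with TMM factors for the values given per group. Where all libraries of a group had 0 reads, the fold was computed against a floor of 3 counts over the group and is given as a lower bound; with 1 to 3 reads, the ratio is given with its exact 95% counting interval. Such intervals and floors cover counting error only, because reads amplified by PCR are not independent molecules.

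Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM factors, a robust quasi-likelihood fit with 1 mean per group (culture, arm and time) and quasi-likelihood F-tests, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. K8484, DT6606 and the organoids were each fitted alone for the IL-1β effect averaged over times, at each time, and for differences of the effect between times. A joint fit of the 33 line libraries tested whether the effect differed between K8484 and DT6606 and how the untreated lines differed. Standard errors (SE) of log2 fold changes were the absolute change over the square root of the F statistic of the same test. Where an arm had few reads, such an SE can be smaller than counting error alone and does not bound the fold. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

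The tests, the genes to be named and 37 gene lists were fixed before the data were examined. Named genes were, for each average effect, the 10 that rose and the 8 that fell with the largest log2 fold change among called genes with a mean of at least 5 CPM in the higher arm and the same sign at every time, leaving out predicted and clone-named genes. To these were added a fixed panel of 17 cytokine and NF-κB response genes, up to 4 members of each list that passed its test and up to 2 of each other list. Up to 3 genes in each direction were named per single time, 6 per test over time, and 6 in each direction per line difference. The lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over lists with at least 5 tested members, and again with a correlation estimated from the data. Counts of members are given over all genes tested and adjusted over the list alone.

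The procedure was tested on simulated counts drawn from the real means, dispersions and library sizes, with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. For the K8484 average effect, 85.1%, 98.5% and 100% of these were recovered, in that order, among 13249 genes. For the organoid effect at 48 h, the comparison with 2 libraries per arm, 26.9%, 65.7% and 86.4% were recovered among 14205 genes. Of the simulated calls, 6.44% were false in the first of these comparisons and 2.46% in the second. Over all comparisons the share ran from 2.46% to 9.41% (DT6606 at 96 h), so it exceeded the threshold in some. Changed genes were drawn only above a low mean expression and were far fewer than the 5336 called for the real K8484 average effect. Noise was independent between genes, without library-wide differences, so these shares may not hold for the real data.

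Alternatives were RLE factors, no expression filter, DESeq2 1.42.0, a replicate block, only the 2 groups compared, estimated correlation for the lists, and leaving out each library in turn. Leaving out 3 organoid libraries that shared a set of low genes, and leaving out 24 h in K8484 or in both lines, were added after seeing the data. No library was left out of the main results.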

Results

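IL-1β is made by myeloid cells in pancreatic tumours and is sensed by epithelial cells through Il1r1, which activates NF-κB. The question addressed was what tumour cells transcribe when IL-1β is added, in a KPC line (K8484), a KC line (DT6606) and KPC organoids. There were 17 libraries of K8484, 16 of DT6606 and 22 of organoids, with 3 libraries per group except for 5 groups of 2. Il1r1 was expressed in all cultures without IL-1β, at 36.4 ± 1.01 CPM (SD, n = 3) in K8484 at 24 h, 71.5 ± 5.75 CPM (n = 3) in DT6606 at 24 h and 41.6 ± 1.76 CPM (n = 3) in organoids at 24 h.

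In K8484, IL-1β turned on genes that were silent or low in untreated cells. They encoded the nitric oxide synthase Nos2, the superoxide and peroxide generators Nox1 and Duox2 with the Duox2 maturation factor Duoxa2, the iron-binding protein Lcn2, the IL-36 cytokine Il1f6 and the surface protein Plet1. Chemokines that attract neutrophils, colony-stimulating factors and complement rose with them, as did interferon-stimulated genes. Genes of mitosis and DNA replication fell together, and the mucin Muc5ac fell.

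Averaged over 24, 48 and 96 h, 5336 of 13590 genes tested differed in K8484, of which 2632 were higher and 2704 lower with IL-1β. Of these, 535 were at least 2-fold higher and 158 at least 2-fold lower. Nos2 (chromosome 11, 78920787 to 78960254) rose by 9.38 ± 0.13 (log2 fold change ± SE, edgeR adjusted p = 4.36e-34), from 0.0779 ± 0.135 to 100 ± 0.706 CPM (SD, n = 3 and 2) at 24 h. Lcn2 (chromosome 2, 32384633 to 32388252) rose by 8.26 ± 0.07 (edgeR adjusted p = 1.17e-28), to 1249 ± 106 CPM (SD, n = 3) at 96 h. Nox1 rose by 9.08, Plet1 by 7.84, Gfi1b, a transcription factor of blood cells, by 7.12, Duox2 by 7.06, Duoxa2 by 6.90 and Vnn3 by 6.83 on the log2 scale. Il1f6 had 0 reads in untreated K8484 at 24 and 48 h, so it was at least 342-fold and at least 295-fold higher with IL-1β at those times. Sprr2h, a cornified envelope gene, had 3 reads in all untreated libraries together, and its ratio was 225 (95% counting interval 76.7 to 1095). For all 10 of these genes the 8 stimulated libraries lay above the 9 untreated ones. Here and in the other cultures, such separation describes genes chosen by size in the same libraries and is no independent evidence.

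The fixed panel moved the same way in K8484 except for the receptor. Cxcl5 (chromosome 5, 90759360 to 90761624) rose by 5.39 ± 0.03 (edgeR adjusted p = 2.59e-46), reaching 3875 ± 116 CPM at 48 h against 86.1 ± 2.18 CPM untreated (SD, n = 3). Il6 rose by 6.72, C3 by 6.80, Saa3 by 6.13, Csf3 by 5.12, Csf2 by 5.02, Cxcl2 by 3.91, Ptgs2 by 3.86, Cxcl1 by 3.24, Ccl2 by 2.86 and Ccl20 by 2.71 on the log2 scale. The NF-κB feedback inhibitors Nfkbia and Tnfaip3 rose by 1.79 and 1.23, Icam1 by 0.96 and the receptor antagonist Il1rn by 0.60. Il1r1 fell by 0.22 (edgeR adjusted p = 0.00792). Of the 17 panel genes, 15 had all stimulated libraries beyond all untreated ones.

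Among the lists in K8484, all 8 tested neutrophil chemokines and colony-stimulating factors rose, over all genes and adjusted over the list alone, with a median log2 fold change of 4.35 (camera adjusted p = 3.82e-121). Of 10 acute phase and antimicrobial genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 6.48e-41). Complement genes rose in 7 of 10 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 7.71e-16). Of 22 interferon-stimulated genes, 19 rose and 3 fell, the same numbers as adjusted over the list alone, with a median of 1.77 (camera adjusted p = 1.36e-34). Oasl2, an antiviral gene (chromosome 5, 114896936 to 114912234), rose by 3.27 ± 0.06 from 7.73 ± 0.464 to 76.4 ± 3.07 CPM at 96 h (SD, n = 3), and Irf7, Rtp4 and Usp18 rose by 2.26, 3.38 and 3.65. The interferon-induced chemokine Cxcl10, by contrast, fell by 1.63 ± 0.31 (edgeR adjusted p = 0.000504). Transforming growth factor-β targets rose in 9 of 11 and fell in 1, the same numbers as adjusted over the list alone (camera adjusted p = 1.80e-14), led by Id3 at 1.89 and Id1 at 1.20. All 20 mitosis genes fell, over all genes and adjusted over the list alone, with a median of -0.51 (camera adjusted p = 1.34e-11). Of 23 DNA replication genes, 21 fell, over all genes and adjusted over the list alone, with a median of -0.58 (camera adjusted p = 3.18e-11), among them Mcm3 by 0.73 and Mcm5 by 0.88. These 7 lists also passed with an estimated correlation. Glycolysis and hypoxia genes rose in 17 of 22, also adjusted over the list alone (camera adjusted p = 3.78e-05; adjusted p = 0.227 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 20 and fell in 1, also adjusted over the list alone (camera adjusted p = 9.35e-05; adjusted p = 0.0807 with an estimated correlation). The IL-1 receptor pathway list did not pass (5 of 18 rose and 2 fell, also adjusted over the list alone; camera adjusted p = 0.501).

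The largest falls in K8484 were smaller than the rises. Muc5ac, a gel-forming mucin (chromosome 7, 141788972 to 141819231), fell by 1.79 ± 0.13 (edgeR adjusted p = 7.38e-14), from 45.2 ± 2.25 to 11.01 ± 2.17 CPM at 96 h (SD, n = 3). Bcas1 fell by 1.96, Cst9 by 1.65, Mep1a by 1.62, Ptgds by 1.52 and Arhgap40 by 1.48 on the log2 scale. The lysozyme gene Lyz2 fell by 2.67 ± 0.67 (edgeR adjusted p = 0.00735), but its log2 fold change was -0.20 when 24 h was left out (edgeR adjusted p = 0.823) and -2.52 with the replicate block (edgeR adjusted p = 0.0719), and untreated K8484 replicate 3 of 48 h also had only 0.461 CPM of Lyz2. Of the 8 genes with the largest falls, 2 had all stimulated libraries beyond all untreated ones and 6 were apart at every single time.

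At single times in K8484, 2397 genes differed at 24 h (1344 higher, 1053 lower; 1192 without stimulated replicate 2), 2672 at 48 h (1511 and 1161) and 3754 at 96 h (2144 and 1610). Nos2 was among the 3 largest rises at every time, at 10.13 ± 0.24, 8.93 ± 0.24 and 9.08 ± 0.22. It had only 4, 5 and 8 untreated reads at these times, so the SE do not bound its folds. Il13ra2, a decoy receptor of IL-13, was at least 121-fold higher at 24 h, where untreated libraries had 0 reads. With 2 untreated reads, Nox1 had a ratio of 918 at 48 h (95% counting interval 254 to 7590). At 96 h the ratio of Saa3 was 788 (141 to 31176) and that of Clca4b was 452 (80.7 to 17875), each with 1 untreated read. Gkn2 at 96 h fell by 2.64 ± 0.39 (edgeR adjusted p = 1.33e-06). At 24 h Gpnmb had 1 read in the stimulated libraries and was 339 times lower (60.6 to 13424), and Lyz2 fell by 7.62 ± 1.56 (edgeR adjusted p = 0.00469); neither passed without stimulated replicate 2, where their log2 fold changes were -10.20 and -11.42 (edgeR adjusted p = 0.104 and 0.0773), or with the replicate block, where they were -8.00 and -7.48 (edgeR adjusted p = 0.0572 and 0.0658). Cxcl10 at 48 h fell by 1.95 ± 0.52 (edgeR adjusted p = 0.0132), and by 1.76 without stimulated replicate 2 (edgeR adjusted p = 0.0720). The effect differed between times for 621 genes: that of Cxcl5 grew from 4.86 to 5.49 and 5.83, that of the retinaldehyde dehydrogenase Aldh1a3 from 1.13 to 2.15 and 3.17, and that of the mitotic topoisomerase Top2a went from 0.04 to -0.48 and -0.97.

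**Figure D1:**
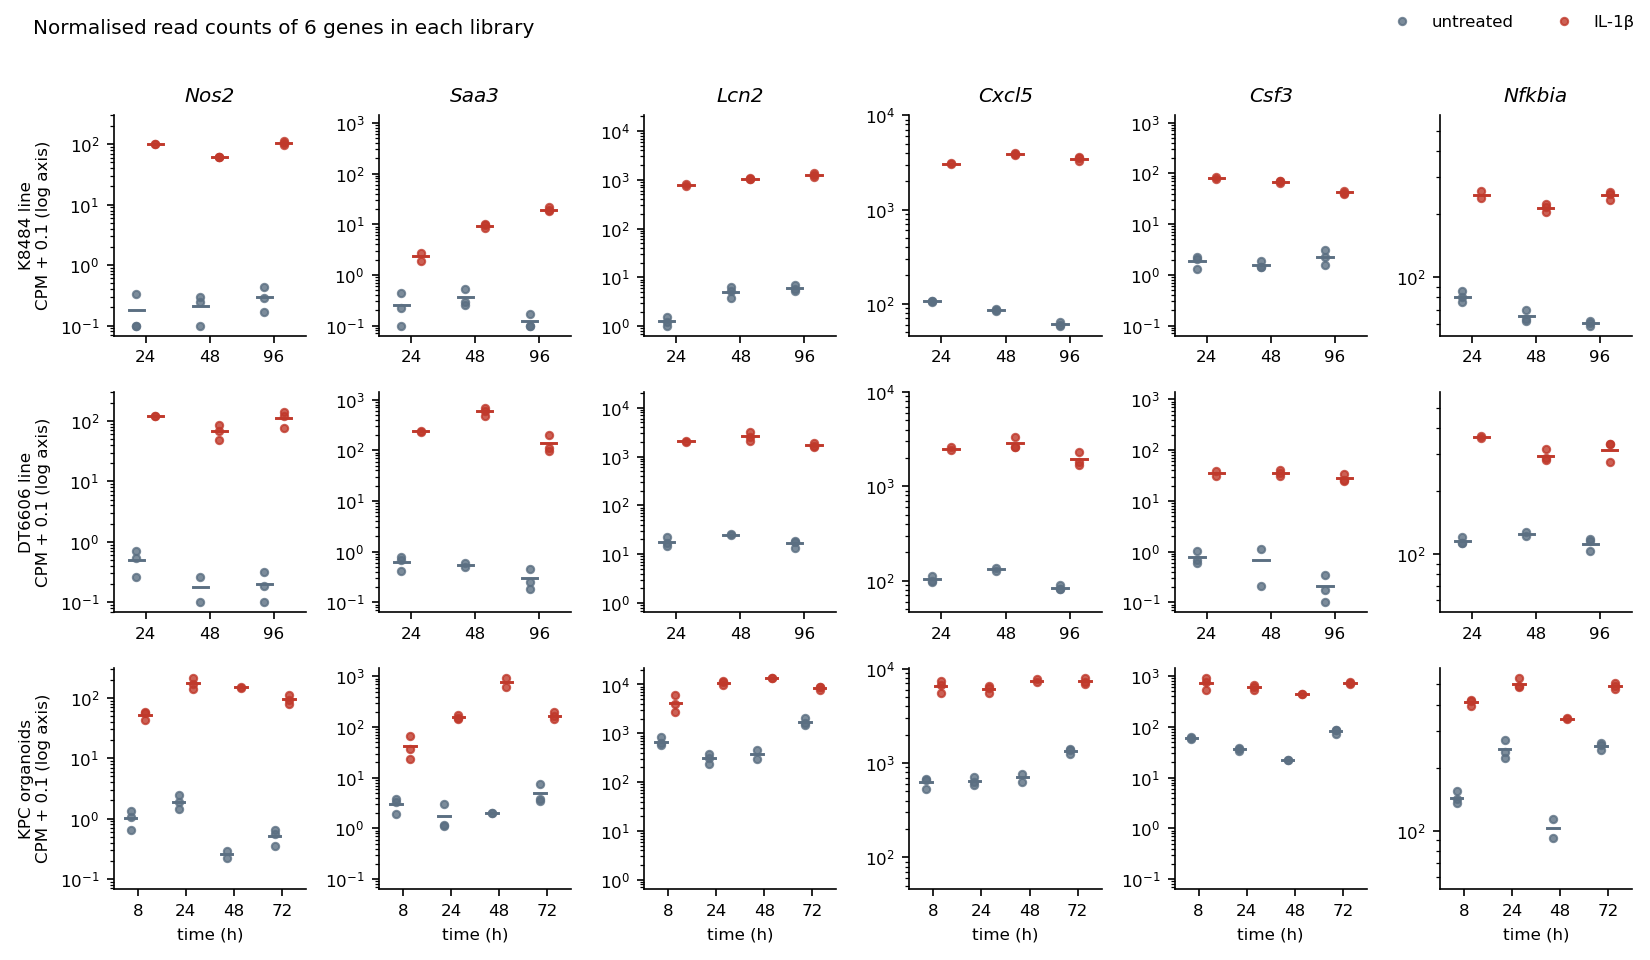
CPM of 6 genes (Nos2, Saa3, Lcn2, Cxcl5, Csf3 and Nfkbia) in each library, plus 0.1 and on a log axis, by culture, time in hours and arm; bars are group means. Untreated Nos2 stayed below 2 CPM in every group mean, while stimulated group means lay between 52.4 and 174 CPM.

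DT6606 responded to IL-1β with a similar set of secreted and antimicrobial proteins, and the matrix metalloproteinases Mmp7 and Mmp9 rose. The acute phase protein Saa3, the iron-binding proteins Ltf and Lcn2 and the chitinase-like protein Chil1 rose from low levels. Ttr, Gc and the ligand Shh fell. The interferon-stimulated list did not pass in this line.

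Over the 3 times, 3105 of 14495 genes differed in DT6606, with 1734 higher and 1371 lower; 485 and 102 of them by at least 2-fold. Saa3 (chromosome 7, 46711998 to 46715700) rose by 9.54 ± 0.27 (edgeR adjusted p = 1.16e-11), from 0.440 ± 0.0622 to 586 ± 106 CPM at 48 h (SD, n = 2 and 3). Mmp7, which cleaves matrix and cell surface proteins (chromosome 9, 7692090 to 7699585), rose by 7.34 ± 0.20 (edgeR adjusted p = 6.57e-17). Nos2 rose by 9.33, Nox1 by 7.15, Ltf by 6.99, Lcn2 by 6.74, Csf3 by 6.57, Mylk2 and Chil1 each by 6.10 and Mmp9 by 5.38. All 10 genes were higher in each of the 8 stimulated libraries than in any of the 8 untreated ones. Ttr (chromosome 18, 20665280 to 20674321) fell by 1.78 ± 0.13 (edgeR adjusted p = 9.22e-10), Shh by 1.57 ± 0.19 (edgeR adjusted p = 1.93e-06), Pzp by 1.77, Olr1 by 1.70, Gc by 1.41, Rhov by 1.31, Igf1 by 1.28 and Npy4r by 1.25. Of these 8 genes, 5 had all stimulated libraries below all untreated ones.

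In the panel, Cxcl5 rose by 4.52 ± 0.08 in DT6606 (edgeR adjusted p = 6.00e-19), Cxcl2 by 4.61, Csf2 by 4.30, Ccl20 by 3.71, C3 by 3.31, Cxcl1 and Ptgs2 each by 3.19, Ccl2 by 2.47, Icam1 by 1.62, Nfkbia by 1.46 and Tnfaip3 by 0.86. Il6 rose by 7.52 ± 0.54 and was at least 48.9-fold higher at 48 h. Il1rn (0.09 ± 0.05, edgeR adjusted p = 0.159) and Il1r1 (-0.08 ± 0.08, edgeR adjusted p = 0.493) did not pass. Of the 17 panel genes, 15 had all stimulated libraries beyond all untreated ones.

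All 9 neutrophil chemokines and colony-stimulating factors tested in DT6606 rose, over all genes and adjusted over the list alone, with a median of 3.72 (camera adjusted p = 4.88e-90). Acute phase genes rose in 9 of 11 (10 adjusted over the list alone; camera adjusted p = 5.65e-50) and complement genes in 7 of 10, also adjusted over the list alone (camera adjusted p = 1.26e-24). Extracellular proteases and inhibitors rose in 11 of 19 and fell in 2, the same numbers as adjusted over the list alone (camera adjusted p = 6.53e-10). These 4 lists also passed with an estimated correlation. Glycolysis genes such as Egln3, Pfkp and Hk2 rose in 17 of 22, also adjusted over the list alone (camera adjusted p = 7.78e-08; adjusted p = 0.170 with an estimated correlation). Unfolded protein response genes rose in 13 of 18 (16 adjusted over the list alone; camera adjusted p = 0.000115; adjusted p = 0.0818 with an estimated correlation). Mitosis genes fell in 7 of 20 (11 adjusted over the list alone; camera adjusted p = 0.00885; adjusted p = 0.400 with an estimated correlation). DNA replication genes fell in 4 of 23, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.167). Interferon-stimulated genes rose in 6 of 20, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0637); Gbp2 rose by 1.44 and Bst2 by 0.78.

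At single times, 1406 genes differed in DT6606 at 24 h (890 higher, 516 lower), 1231 at 48 h (783 and 448) and 1482 at 96 h (967 and 515). Without stimulated replicate 1 or 2 the count at 24 h was 685 or 729; at 48 h it was 611 or 600 without untreated replicate 1 or 2 and 2268 without stimulated replicate 3. With only the 2 groups compared, the counts were 3187 at 24 h and 383 at 48 h, so the times cannot be ranked by them. Saa3 and Nos2 were the 2 largest rises at each time; at 48 h Nos2 had 2 untreated reads and a ratio of 1022 (95% counting interval 283 to 8446). Mmp7 at 96 h, with only 4 untreated reads, rose by 8.70 ± 0.36 (edgeR adjusted p = 4.28e-13) and Shh fell by 2.28 ± 0.33 (edgeR adjusted p = 4.55e-05). Igf1 at 24 h fell by 2.11 ± 0.18 (edgeR adjusted p = 1.80e-08), and Nptx1 fell by 2.09 ± 0.44 (edgeR adjusted p = 0.00313), and by 1.71 without stimulated replicate 2 (edgeR adjusted p = 0.0929). Rhov at 48 h fell by 1.80 ± 0.35 (edgeR adjusted p = 0.00156), and by 1.82 when only the 2 groups compared were fitted (edgeR adjusted p = 0.149). The effect differed between times for 121 genes, a count that ranged from 29 (without stimulated replicate 2 of 24 h or untreated replicate 2 of 96 h) to 332 (without stimulated replicate 2 of 48 h) when 1 library was left out and was 611 without a filter: that on the secreted glycoprotein Lrg1 was 4.98, 4.31 and 2.89, that on the water channel Aqp8 was -1.99, -1.27 and 0.38, and those on the mitotic genes Ccna2 and Plk1 were 0.18 and 0.19 at 24 h and -0.83 and -0.81 at 96 h.

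In organoids, IL-1β raised the neutrophil-type proteins S100a8, S100a9 and Cd177 along with Nos2, Saa3 and Plet1. Chemokines and colony-stimulating factors rose, with Csf3 and Cxcl5 ahead. Alb, Ttr and Cyp2b10 fell. DNA replication genes fell, and unfolded protein response genes rose.

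Over 8, 24, 48 and 72 h, 4927 of 14615 genes differed in organoids, 2386 higher and 2541 lower; 402 and 321 of them by at least 2-fold. S100a8 (chromosome 3, 90668978 to 90670035) rose by 7.98 ± 0.26 (edgeR adjusted p = 1.85e-12), to 3.80 ± 2.16 CPM at 8 h and 267 ± 10.1 CPM at 72 h, against 0.351 ± 0.184 CPM untreated at 72 h (SD, n = 3). S100a9, its binding partner, rose by 7.08, Nos2 by 7.53, the phosphate transporter Slc34a2 by 7.23, Cd177 by 6.31, Saa3 by 6.05, Steap4 by 5.95, Tmprss11g by 5.36, Plet1 by 5.07 and Nox1 by 4.86. Of these 10 genes, 9 had all 11 stimulated libraries above all 11 untreated ones. Alb (chromosome 5, 90460897 to 90476602) fell by 4.27 ± 0.36 (edgeR adjusted p = 6.27e-09); in untreated organoids it was 0.278 ± 0.0341 CPM at 8 h and 30.5 ± 7.52 CPM at 72 h, where it was 0.102 ± 0.0907 CPM with IL-1β (SD, n = 3). Ttr fell by 2.78 ± 0.07 (edgeR adjusted p = 6.57e-16), Ddc by 2.36, Cyp2b10 by 2.15, Enpp2 by 2.10, Ces2a by 2.06, Gal3st2 by 1.94 and Cyp2d26 by 1.90. None of these 8 had all stimulated libraries below all untreated ones across times, but 7 were apart at every single time.

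Of 16 panel genes tested in organoids, all rose: Lcn2 by 3.81, Csf3 by 3.79, Ptgs2 by 3.56, Cxcl5 by 3.12 ± 0.07 (edgeR adjusted p = 4.01e-17), C3 by 2.57, Csf2 by 2.31, Cxcl2 by 2.21, Ccl20 by 1.68, Cxcl1 by 1.59, Tnfaip3 by 1.39, Icam1 by 1.34, Nfkbia by 1.31, Il1r1 by 0.90, Ccl2 by 0.86 and Il1rn by 0.81, with Saa3 as above. Il6 was too low to be tested. Of these 16 genes, 9 had all stimulated libraries above all untreated ones and 13 were apart at every time.

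Acute phase and antimicrobial genes rose in 12 of 15 in organoids, also adjusted over the list alone, with a median of 2.82 (camera adjusted p = 3.67e-19). Neutrophil chemokines and colony-stimulating factors rose in 8 of 9, also adjusted over the list alone (camera adjusted p = 1.30e-16). The IL-1 receptor pathway rose in 8 of 19 and fell in 2, the same numbers as adjusted over the list alone (camera adjusted p = 0.000823), with Irak2 at 0.75. Unfolded protein response genes rose in 16 of 18 (18 adjusted over the list alone; camera adjusted p = 8.87e-12), led by Herpud1 at 1.27, and DNA replication genes fell in 20 of 23 and rose in 1, also adjusted over the list alone (camera adjusted p = 4.61e-10). These 5 lists also passed with an estimated correlation. Glycolysis genes rose in 19 of 22, also adjusted over the list alone (camera adjusted p = 2.48e-12; adjusted p = 0.0772 with an estimated correlation), with Hk2 at 1.35 and Bnip3 at 1.49. Mitosis genes fell in 13 of 20 (16 adjusted over the list alone; camera adjusted p = 3.01e-05; adjusted p = 0.230 with an estimated correlation). Targets of p53 fell in 8 of 19 and rose in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0249; adjusted p = 0.0880 with an estimated correlation). Interferon-stimulated genes did not pass over the times (4 of 22 rose, also adjusted over the list alone; camera adjusted p = 0.237).

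At single times in organoids, 2332 genes differed at 8 h (1159 higher, 1173 lower), 2290 at 24 h (1147 and 1143), 2285 at 48 h (1412 and 873; 1144 without untreated replicate 1, and 1484 or 1423 without stimulated replicate 1 or 2) and 2566 at 72 h (1336 and 1230). At 8 h Steap4 rose by 6.16 ± 0.54 and Nos2 by 5.91 ± 0.28, while the water channel Aqp1 fell by 2.19 ± 0.23. At 24 h Ttr fell by 3.98 ± 0.14 and the protease inhibitor Serpina5 fell by 5.82 ± 0.62. At 48 h Slc34a2 was at least 205-fold higher, with 0 untreated reads, and Dcpp3 fell by 4.26 ± 0.91 (edgeR adjusted p = 0.00249), by 2.06 without untreated replicate 2 (edgeR adjusted p = 0.180), and by 4.27 when only the 2 groups compared were fitted (edgeR adjusted p = 0.273). At 72 h Alb fell by 8.03 ± 0.53 (edgeR adjusted p = 1.17e-09), the apolipoprotein Apoc1 by 4.37 and Enpp2 by 4.09. The effect differed between times for 1803 genes (1002 with the replicate block). That on Plet1 was 5.36, 5.54, 6.50 and 2.89, that on the laminin chain Lamb3 was 0.49, 1.38, 2.42 and 1.09, and that on the lipid carrier Fabp5 was 0.08, 0.83, 2.16 and 0.95. The labels do not say whether the times, among them 48 h with its smaller groups, came from the same set of cultures. Time and set of cultures therefore cannot be told apart.

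**Figure D2:**
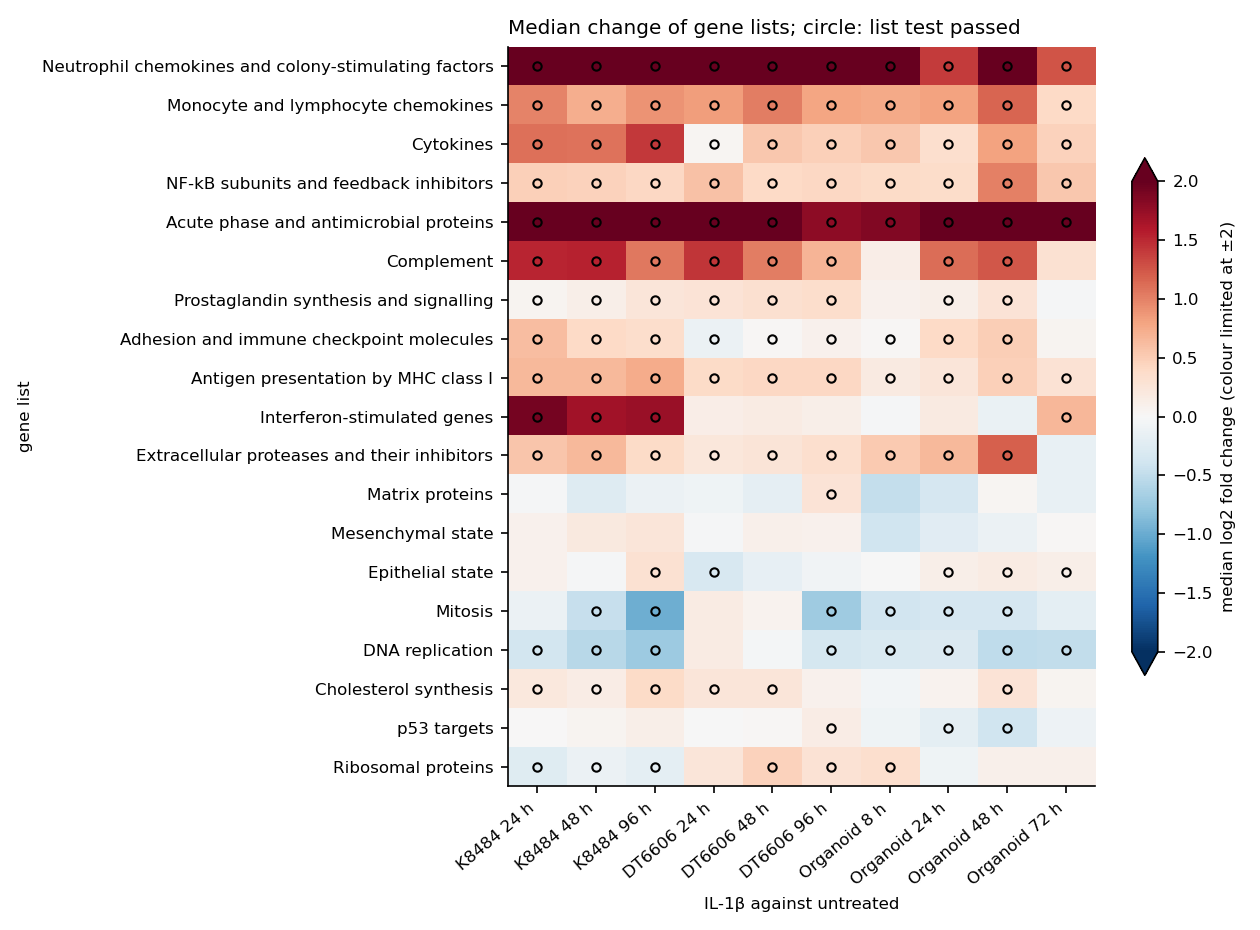
Median log2 fold change with IL-1β of each gene list (colour, limited at -2 and 2) by culture and time in hours; circles mark lists whose camera test passed. Neutrophil chemokines and acute phase genes were raised in all 3 cultures, and the interferon-stimulated list passed at every time in K8484, at 72 h in organoids and at no time in DT6606.

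The 3 cultures shared part of their response. Of 12496 genes tested in all, 593 were higher with IL-1β in all 3, against 48.3 if calls were independent, and 241 were lower in all, against 42.4. Among the shared rises, 41 genes were at least 4-fold higher in each culture, and these included Nos2, Saa3, Nox1, Ltf, Chil1, Plet1, Slc34a2, Tmprss11g, Vnn3, Lrg1 and Mmp7, the oxidase gene Duox2, and Csf3, Csf2, Cxcl5, Cxcl2 and Ptgs2 of the panel. K8484 and DT6606 shared 890 higher genes (291 expected) and 484 lower genes (252 expected) of 12958, while 165 genes were higher in K8484 and lower in DT6606 (242 expected). Genes are not independent of each other, so these expectations carry no p-value.

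The size of the response differed between the lines. Interferon-stimulated genes, transforming growth factor-β targets such as Id3 and the oxidase Duox2 had a higher effect in K8484, while the monocyte chemokine Ccl7 had a higher effect in DT6606. Genes of DNA replication and mitosis had a lower effect in K8484, where they fell; in DT6606 the DNA replication list did not pass. Each genotype was represented by a single line, so line and genotype cannot be separated.

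The effect of IL-1β differed between K8484 and DT6606 for 3131 of 15240 genes, 1543 with a higher and 1588 with a lower log2 fold change in K8484, and for 1966 without 24 h. Clca3a1, of a family of secreted chloride channel regulators, had log2 fold changes of 5.13 in K8484 and 0.43 in DT6606, a difference of 4.70 ± 0.28 (edgeR adjusted p = 1.08e-15). Hmgcs2, the ketone body enzyme, differed by 4.30 ± 0.27 (edgeR adjusted p = 1.76e-15) and Duox2 by 4.0 ± 0.26 (edgeR adjusted p = 5.73e-15), while Dscaml1 and Megf10 differed by 4.58 and 4.51. Il1f6 differed by 4.46 ± 1.33 (edgeR adjusted p = 0.0149), and by 3.18 without 24 h (edgeR adjusted p = 0.169). Ccl7 (chromosome 11, 82045712 to 82047525) rose to 61.0 ± 13.9 CPM in DT6606 at 48 h from 3.06 ± 1.37 CPM (SD, n = 3 and 2), was too low to be tested in K8484 alone, and differed by -6.22 ± 0.65 (edgeR adjusted p = 5.45e-09), and by -4.19 without 24 h (edgeR adjusted p = 0.000258). Acod1, Dock10 and Sirpa differed by -5.72, -5.14 and -4.35. Acod1 and Sirpa were called in K8484 at 24 h alone, where both stimulated libraries had 0 reads of them, and their differences were -3.46 and -2.24 without 24 h (edgeR adjusted p = 0.00819 and 0.00582). Dock10 differed by -3.75 without 24 h (edgeR adjusted p = 0.00368). Serpina3g (-4.68 ± 1.55, edgeR adjusted p = 0.0269) and Ch25h (-4.0 ± 1.16, edgeR adjusted p = 0.0119) differed by -4.52 and -2.96 without 24 h (edgeR adjusted p = 0.140 and 0.167), and Serpina3g by -4.35 without untreated K8484 replicate 1 of 24 h (edgeR adjusted p = 0.0511) and by -4.83 with the replicate block (edgeR adjusted p = 0.0533). In 6 further fits without 1 library, the group that lost it was left with 0 reads, from 1 to 5 before, and the edgeR adjusted p was 1.00. These were Il1f6 without untreated DT6606 replicate 1 of 48 h (3.71) or of 96 h (3.51), Dock10 (-3.83) and Ch25h (-3.35) without untreated K8484 replicate 1 of 48 h, and Serpina3g (-4.04) and Ch25h (-3.09) without untreated K8484 replicate 2 of 96 h. The F statistic was at most 0.000106 there although the fitted differences stayed large, so these fits leave the calls open.

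Interferon-stimulated genes had a higher effect in K8484 in 18 of 22 (19 adjusted over the list alone, with 1 lower), with a median difference of 1.48 (camera adjusted p = 1.26e-32). Oasl2 differed by 2.83 ± 0.12 (edgeR adjusted p = 3.69e-20), Ddx58 by 1.96 and Stat1 by 1.73. Transforming growth factor-β targets were higher in 8 of 11 and lower in 1, the same numbers as adjusted over the list alone (camera adjusted p = 1.15e-12), with Id3 differing by 1.54. DNA replication genes had a lower effect in 16 of 23 (19 adjusted over the list alone; camera adjusted p = 2.14e-13) and mitosis genes in 17 of 20, also adjusted over the list alone (camera adjusted p = 3.69e-09). These 4 lists also passed with an estimated correlation. Ribosomal protein genes had a lower effect in 23 of 24 (24 adjusted over the list alone; camera adjusted p = 2.61e-13; adjusted p = 0.183 with an estimated correlation). The acute phase list passed upwards (camera adjusted p = 0.000795; adjusted p = 0.0215 with an estimated correlation), with 4 of 13 genes higher and 1 lower, also adjusted over the list alone, although its median difference was -0.37; Lbp, which binds lipopolysaccharide, differed by 2.20.

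Without IL-1β, most genes tested differed between the lines. K8484 expressed more of the gastric-type claudin Cldn18, the mucin Muc1 and cholesterol synthesis enzymes, while DT6606 expressed more matrix genes, mesenchymal regulators such as Zeb2 and Snai1, and complement. A block of neighbouring genes on chromosome 4 around the tumour suppressor Cdkn2a was nearly silent in DT6606.

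Untreated, 11309 of 15240 genes differed, 5205 higher and 6104 lower in K8484. Cdkn2a (chromosome 4, 89274471 to 89294653) was higher in K8484 by 10.81 ± 0.19 (edgeR adjusted p = 2.38e-32), Cdkn2b by 11.03 and Mtap by 11.10. Wincr1 (chromosome 4, 89050308 to 89084614) had 0 reads in untreated DT6606 and was at least 287-fold higher in K8484; Dmrt3 also had 0 reads and was at least 390-fold higher. With the replicate block, edgeR adjusted p was 1.00 for both, at fitted log2 differences of 9.73 and 10.36, with an F statistic near 0 as in the fits above. Xist was higher by 10.09. The collagen gene Col5a2 had 2 reads in untreated K8484 and a ratio of 3566 in favour of DT6606 (95% counting interval 987 to 29451), and Crp had 1 read and a ratio of 4564 (819 to 180313). Dio3os and Acot1 had 0 reads in untreated K8484 and were at least 1199-fold and at least 1145-fold higher in DT6606. Fstl1 and Igfbp3 differed by -11.36 and -11.19. Sparc, a collagen-binding matrix protein (chromosome 11, 55394500 to 55423183), differed by -8.49 ± 0.09 (edgeR adjusted p = 2.20e-41), with 0.160 ± 0.0387 CPM in K8484 and 161 ± 10.9 CPM in DT6606 at 24 h (SD, n = 3).

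All 20 cholesterol synthesis genes were higher in untreated K8484, over all genes and adjusted over the list alone, with a median of 1.57 (camera adjusted p = 3.34e-23). Matrix genes were lower in 10 of 16 and higher in 5 (camera adjusted p = 4.59e-07), mesenchymal state genes lower in 11 of 13 and higher in 1 (camera adjusted p = 6.29e-05) and complement genes lower in 6 of 10 and higher in 1 (camera adjusted p = 2.90e-05), with the same numbers adjusted over each list alone. These 4 lists also passed with an estimated correlation. The classical pancreatic cancer program was higher in 8 of 19 and lower in 7 (9 and 7 adjusted over the list alone; camera adjusted p = 0.00951; adjusted p = 0.152 with an estimated correlation), with Cldn18 at 8.57 and Muc1 at 3.70. The cytokine list did not pass (camera adjusted p = 0.858), although Tnf was higher by 3.97 and the chemokine Ccl2, of another list, was lower by 6.15 on the log2 scale.

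**Figure D3:**
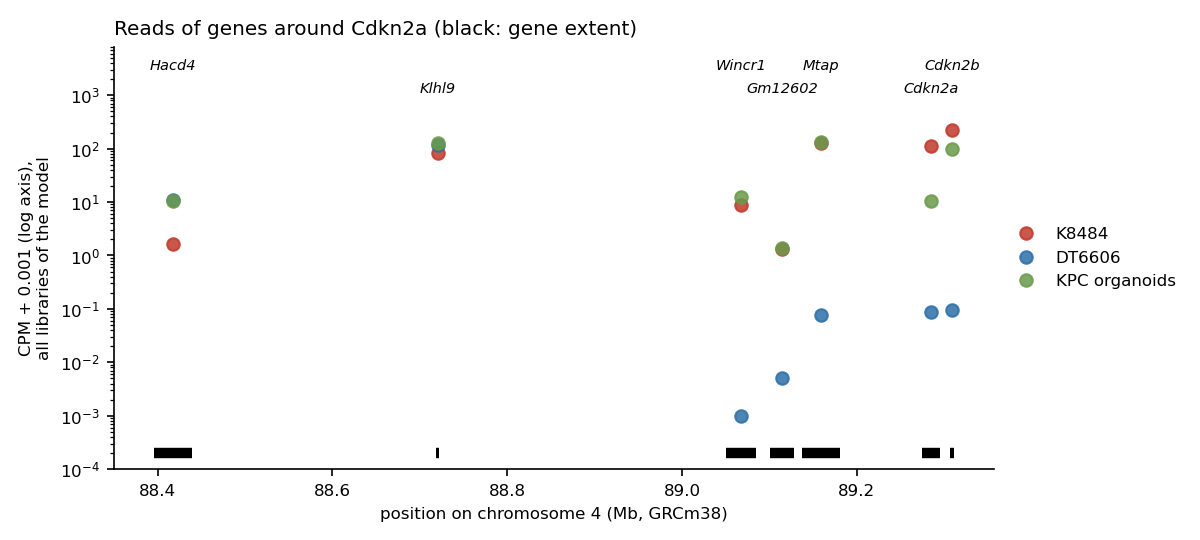
CPM plus 0.001, on a log axis, of genes around Cdkn2a against position on chromosome 4 (GRCm38), for K8484, DT6606 and organoids over all libraries. From Wincr1 to Cdkn2b, DT6606 lay at or below 0.0954 CPM, while Klhl9 (ending at 88722465) and Caap1 (starting at 94500081), the nearest genes on either side with at least 100 reads in K8484 and in organoids, were expressed. Caap1 lies outside the plotted range and is not drawn.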

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

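All tests that weigh explanations for the last 3 patterns of this part were chosen after their results had been seen, as was the look at which arms the largest splits exchanged; the counts over other splits of the libraries were planned.

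The effect of IL-1β differed between times in each culture by a test of the interaction itself. In K8484 this held for 621 genes, with the smallest edgeR adjusted p for Cdh17 (1.945e-10), Cxcl5 (1.945e-10), Mrc1 (1.806e-09), Top2a (1.806e-09), Pparg (2.634e-09) and Aldh1a3 (5.673e-09). Cdh17 went from -0.25 at 24 h to 0.64 at 96 h on the log2 scale, Mrc1 from 0.63 to 2.29 and Pparg from -0.06 to 0.86. In DT6606 it held for 121 genes, led by Aqp8 (0.0005017), Lrg1 (0.0005017), Ccna2 (0.0006859), Pbk (0.001146), Timp3 (0.001371) and Plk1 (0.001371). In organoids it held for 1803 genes (1002 with the replicate block), led by Krt23 (1.016e-07), Lamb3 (1.016e-07), Tnip3 (4.838e-07), Plet1 (4.838e-07), Fabp5 (6.482e-07) and Neurl3 (6.482e-07). Tnip3 had effects of 1.98, 2.04, 3.39 and 1.87, Krt23 of -0.39, 0.05, -0.06 and 1.08, and Neurl3 of 1.35, 0.54, 1.08 and 0.06. The labels do not say whether the times of a model came from the same set of cultures, so time and set of cultures cannot be told apart.

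The effect of IL-1β also differed between the lines, for 3131 genes (1966 without 24 h). It was larger in K8484 for Clca3a1 (4.697), Dscaml1 (4.581), Megf10 (4.506), Il1f6 (4.462), Hmgcs2 (4.302) and Duox2 (4.0), and lower in K8484 for Ccl7 (-6.215), Acod1 (-5.721), Dock10 (-5.142), Serpina3g (-4.684), Sirpa (-4.349) and Ch25h (-3.998), all on the log2 scale. Without 24 h, Il1f6, Serpina3g and Ch25h did not pass (3.18, -4.52 and -2.96; edgeR adjusted p = 0.169, 0.140 and 0.167).

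Other splits of the same libraries into groups of the same sizes were counted, with the real split included. Chance here means the spread between these libraries. The labels do not say whether replicates were separate cultures, so chance differences between cultures were not covered. Chance could be excluded for the average effects in K8484 (5336 genes, 2526 in the highest other split; 1 of 100 splits as large), DT6606 (3105 and 573; 1 of 100) and organoids (4927 and 3639; 1 of 100). It could also be excluded for the untreated lines, fitted on untreated libraries alone (11651 genes, 7542 in the highest other split, 1 of 60 splits as large). In these comparisons the splits would be interchangeable if arm or line made no difference, so the rank of the real split answers that question. For the difference between times, 5 of 100 splits were as large in K8484 (621 and 2684), 3 of 100 in DT6606 (121 and 2883) and 1 of 100 in organoids (1803 and 815). The highest counts in the lines reflect a structure of the samples that the arms themselves supply: both splits kept the real arms at 24 h and exchanged them at 96 h, which turns the IL-1β effect into a difference between times, and each called 32 genes on average over times. Such splits move the IL-1β effect between times in organoids too. Other splits also mix the arms within groups, which widens the spread and can lower their counts, so the rank of 1803 in organoids is not decisive. These counts therefore do not decide whether chance can be excluded for the difference between times in any culture. The counts for the difference between lines (3131 genes, 88 in the highest other split, 1 of 60 splits as large) do not decide it either. Those splits also mixed the arms within groups. In DT6606 the count for the difference between times fell to 29 without untreated replicate 2 of 96 h. With 10 splits, a single time had too few for a share under 0.05. The real count was the largest, 1 of 10, in K8484 at 48 h (2672, other 1) and 96 h (3754, other 128), in DT6606 at 96 h (1482, other 0) and in organoids at 8 h (2332, other 1), 24 h (2290, other 0) and 72 h (2566, other 7).

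Genes typical of macrophages (Lyz2, Gpnmb, C1qb, Tyrobp and Csf1r) summed to 11.9 to 57.1 CPM in 14 of 17 K8484 libraries but to 0.164 and 0.400 CPM in both stimulated libraries of 24 h. An effect of IL-1β on tumour cells as the whole cause is argued against by untreated K8484 replicate 3 of 48 h, at 3.31% of the median untreated library, and by untreated DT6606 replicate 1 of 48 h, at 0.724 CPM. Reads from macrophages remain open: over 17 and 18 of 19 further macrophage genes with at least 20 reads, the median Spearman rho with Lyz2 was 0.465 in K8484 and 0.289 in DT6606. The genes differed widely, with rho above 0 for 14 of 17 in K8484 and 13 of 18 in DT6606. It ran from -0.333 (Aif1) to 0.880 (Trem2) in K8484 and from -0.409 (Fcgr3) to 0.903 (Ctss) in DT6606. Tumour cells may express part of these further genes themselves. Their sum followed Lyz2 in K8484 (r = 0.598, 2-sided permutation p = 0.0112, 0.0223 adjusted over both lines, and rho = 0.552, permutation p = 0.0247). Without the 2 farthest libraries r was 0.258, so the relation rested on them. In DT6606 r was 0.316 (permutation p = 0.234) and rho was 0.218 (permutation p = 0.419). Single abundant genes made up most of these sums, Cd53 in K8484 (4828 reads, rho 0.461) and Cybb in DT6606 (26590 reads, rho 0.191). The sums therefore do not weigh for or against reads from macrophages. In libraries with at least 50 Lyz2 reads, Gpnmb was 28.0 to 68% of Lyz2 in K8484 and 23.9 to 46.6% in DT6606. Both genes thus moved together in both lines, which does not name their source. What supplied the transcripts typical of macrophages cannot be told apart here. This covers the falls of Lyz2, Gpnmb and Apoe at 24 h in K8484. It also covers the 24 h part of the line differences of Acod1 (-5.72, and -3.46 without 24 h) and Sirpa (-4.35 and -2.24), which had 0 reads in the same 2 libraries.

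In organoids, 214 of 8004 genes, chosen for being at least 4-fold lower in untreated replicate 2 of 24 h than in the other replicates of its group, were also mostly low in untreated replicate 1 of 8 h (median -2.57 on the log2 scale, 96.3% of them under -1) and stimulated replicate 2 of 72 h (-1.54, 74.8%). IL-1β or time is argued against by the untreated 8 h library, at -2.57 against replicates of the same group, and lower depth by the totals of the 3 libraries, 24.5, 27.8 and 19.8 M reads against a median of 16.4 M in the others. A candidate explanation is poor amplification of GC-rich stretches, since the highest GC share of any window of 100 bases separated the low genes from the others with an area under the curve of 0.801 (medians 80.5 and 72.0%). It leaves open why only 8.24% of genes with such windows were low. None of the genes named for organoids belonged to the set, but of 103 that were abundant enough to look at, Tnfaip3 was also at least 1.5-fold lower in all 3 libraries (-1.26, -1.16 and -0.73), and its effect was 1.28 without them (1.39 reported); no biological explanation beyond arm and time was tested.

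Cdkn2a and its neighbours were near 0 in DT6606 over an unbroken run of 5 genes (Wincr1, Gm12602, Mtap, Cdkn2a and Cdkn2b; chromosome 4, 89050308 to 89311039), with 0, 1, 18, 21 and 23 reads over all DT6606 libraries. A fault of mapping or annotation is argued against by K8484, where each gene of the run had at least 330 reads. A lost segment is a candidate explanation, since 5 genes in a row were affected, among those with at least 100 reads in K8484 and in organoids, while Klhl9 (ending at 88722465) and Caap1 (starting at 94500081) were expressed, which leaves the far edge unbounded up to Caap1, and only 6 of 750 genes looked at on chromosome 4 were at 1% or less of K8484. Silencing without loss of DNA cannot be told apart from it, because the highest level in the run, 0.316% of K8484, is one that silenced genes could also show, and RNA gives no copy number.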

How the results depend on the processing

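Leaving out 3 organoid libraries and leaving out 24 h were chosen after seeing the data; the other alternatives were planned. With RLE factors all 19 counts stayed within 1.5 times their reported value, and all 673 gene values kept direction and call. With DESeq2 17 of 18 counts and 671 of 673 gene values did so, and without a filter 17 of 18 and 668 of 673; the exception was the difference between times in DT6606 (121 genes), at 309 with DESeq2 and 611 without a filter. No pairing by replicate number was seen, since none of 26 same-numbered pairs had a correlation above 0.1 (0 of 26). Low correlations cannot show that equal numbers were unrelated, and the pairs of a time are not independent of each other. With the numbers as a block, 17 of 19 counts stayed, DT6606 at 48 h went from 1231 to 1954 and the difference between times in organoids from 1803 to 1002. Fitting only the 2 groups compared gave 3187 genes in DT6606 at 24 h (1406 reported) and 383 at 48 h (1231 reported). Without 24 h, the difference between lines fell to 1966 genes from 3131, with fewer libraries. Of 268 list calls in 488 tests, 151 remained with an estimated correlation, and none was gained; the block lost 8 and gained 4, and RLE factors lost 2. Without the 3 organoid libraries, 7 of 91 list calls in organoids were lost and 8 gained. Without 1 library at a time, 194 of 215 counts stayed within 1.5 times. K8484 at 24 h ranged from 1192 (without stimulated replicate 2) to 2323, DT6606 at 24 h from 685 (without stimulated replicate 1) to 1036, and organoids at 48 h from 1144 (without untreated replicate 1) to 1953. DT6606 at 48 h ranged from 600 (without untreated replicate 2; 611 without replicate 1) to 2268 (without stimulated replicate 3). The lowest of each of these 4 ranges, and every such fit of organoids at 48 h, left 1 library in an arm, which was assumed to vary like the other groups. The difference between times in DT6606 ranged from 29 (without stimulated replicate 2 of 24 h) to 332 (without stimulated replicate 2 of 48 h). Gene values that reversed did not pass in either direction: Bhlha15 ranged from -0.13 to 1.13 in DT6606, from -0.19 to 0.66 in organoids and from -0.48 to 0.78 (with -0.08 among them) for the line difference, and Acta2 from -0.19 to 0.62 in organoids. List tests that reversed did not pass either. With the block their adjusted p were 0.952 (epithelial state, K8484 24 h), 0.866 (matrix, DT6606), 0.872 and 0.647 (classical program and mitochondrially encoded genes, DT6606 48 h), 0.999 (basal-like program, organoids) and 0.991 (growth factors, organoids 24 h), and with RLE factors 0.999 (antioxidant response, untreated lines). Without the 3 organoid libraries they were 0.642 (matrix) and 0.825 (basal-like) on average, 0.858, 0.911 and 0.850 (basal-like, transforming growth factor-β targets and mitochondrially encoded genes) at 8 h, 0.994 and 0.994 (matrix and mesenchymal state) at 24 h and 0.982 (basal-like) at 72 h. Of 201 values of genes named by size, panel or smallest p, 188 kept their call throughout. The causes of these changes were not tested.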

Other observations

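The values in this part were chosen after the data were seen.

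The proliferation marker Mki67 was low in the organoid libraries of 72 h, in both arms. Untreated organoids had 124 ± 14.6 CPM at 8 h, 66.9 ± 3.58 at 24 h, 136 ± 13.1 at 48 h and 3.26 ± 1.85 at 72 h (SD, n = 3, 3, 2 and 3), and stimulated organoids had 83.6 ± 3.40, 51.7 ± 5.14, 79.4 ± 0.332 and 1.14 ± 0.266 CPM. The labels do not say whether the times came from the same set of cultures, so a change over time is not shown. The IL-1β effects in organoids at 72 h, such as the lower Alb, were therefore measured in cultures with little Mki67.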
